A study of Mus musculus with 54 samples.

How the data were processed

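RNA was measured by 3′ end sequencing (QuantSeq, which counts reads near the polyadenylated end of each transcript) in 54 libraries of mouse embryonic stem cells, 3 in each of 18 groups. The libraries form 2 series of 27. Per the labels, the Ezh2 series uses cells that lack Ezh1 and Ezh2 and carry an empty vector (EV), Ezh2 (WT) or Ezh2 with its automethylated lysines changed to arginine (amKR). The Suz12 series uses cells that lack Suz12 and carry an empty vector (EV), Suz12 (WT) or a Suz12 form made to prevent dimerization of the complex (ddim). Cells were collected on days 0, 1 and 4 after the medium that maintains stem cells was replaced by medium with 0.1 µM retinoic acid. EV in one series is therefore a different line from EV in the other.

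The authors deposited 54 tables of counts per gene and 12 lists of gene symbols, and all 66 files were used. The deposited counts are whole numbers without normalization, with the special rows of an HTSeq-type counter. The labels name the mouse genome build mm10 but neither the aligner nor the annotation. The 12 deposited lists (unit: other, gene symbols without numbers) carry WTvsKO or WTvsamKR, up or down and a day in their titles, and the authors state no test, threshold or direction for them. Each table holds 55487 Ensembl gene IDs, of which 55141 matched a symbol in the reference table. Counts on genes ranged from 4223028 to 5111007 per library in the Ezh2 series and from 3801446 to 4462441 in the Suz12 series. Total reads entering each table were almost level within a series, between 7996693 and 8002940 and between 6997715 and 7001555. Reads outside annotated genes took 14.55% to 22.75% and 13.35% to 19.83%, and reads with more than one alignment took 16.93% to 22.13% and 17.07% to 23.27%. A gene with no count in a group of 3 libraries may still have had up to 3 counts, or up to 0.198 to 0.235 CPM (gene counts scaled to a common library size) in the Ezh2 series and 0.225 to 0.259 CPM in the Suz12 series. These floors, and every interval on a count, cover counting error only.

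Each series was fitted on its own in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, which left 14086 genes in the Ezh2 series and 14442 in the Suz12 series. Library sizes were scaled by TMM. A quasi-likelihood model with one mean per group was fitted over 27 libraries, and each comparison was a contrast of those means, tested on both sides. P-values were adjusted over all genes tested by Benjamini and Hochberg, and an adjusted p under 0.05 was a call. The comparisons were EV and mutant against WT and mutant against EV on each day, WT on days 1 and 4 against day 0, and the difference between the day 4 and day 0 effects of EV and of the mutant. Log2 CPM used a prior count of 2. Group means are given as mean ± SD of 3 libraries in CPM, and log2 changes with their standard error (SE). A p-value measures only the spread between these libraries, since the labels do not say whether the 3 of a group came from separate cultures. Replicate numbers paired libraries in 2 of 36 pairs of groups in the Ezh2 series and in 0 of 36 in the Suz12 series, so no pairing was used.

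17 gene lists were fixed before the data were examined: PRC2 subunits, naive pluripotency, general pluripotency, formative and primed pluripotency, retinoic acid response, Hox genes, bivalent developmental transcription factors, extraembryonic endoderm, trophectoderm, neural differentiation, mesoderm and primitive streak, germline genes, 2-cell-like genes, cell cycle inhibitors and p53 targets, imprinted genes, fibroblast and feeder markers, and housekeeping controls. Each was tested with camera in limma 3.58.1, which asks whether a list moved more than the other genes, with a preset correlation of 0.01, and the p-values were adjusted over the lists. No list past the threshold had a median or a mean of the opposite sign to its test. Not every list past the threshold is named for comparisons with EV, for differences between days and for the time course of the Suz12 series, and a list that is named and did not hold with an estimated correlation is given with that p.

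The genes named were chosen by a rule set at the same time. Against WT and over time these are the 8 largest rises and falls among called genes whose libraries do not overlap and whose mean is at least 5 CPM, without predicted genes, and up to 3 called members of each list. Ezh1, Ezh2, Suz12 and Eed are always reported. Against EV it is the 5 largest each way, and for differences between days the 5 with the smallest p each way. Some genes that met this rule are not reported here, and no others were taken in their place. Chance alone would give non-overlapping libraries to 10% of genes in a comparison of 3 against 3.

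The effects of EV and the mutant share a control, so their overlap was set beside 20 simulations with no true effect and, added after the values were seen, 20 in which EV keeps the effects of its called genes and those of the mutant fall on random genes. A signature from each series, the genes called higher in its EV by at least 1 on the log2 scale, was scored in the libraries of the other series. The same calls were compared between series and with the deposited lists. The pipeline was tested on simulated data with the dispersion of each series. False calls made up 4.73% and 3.66% of calls, and genes changed by 0.5, 1 and 2 on the log2 scale were recovered in 30.9%, 83.3% and 98.5% of cases in the Ezh2 series and in 45.6%, 92.4% and 100% in the Suz12 series.

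The alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the libraries compared, a replicate block (overall and within line), leaving out each library in turn, an estimated correlation, a replicate block in camera, fry in place of camera (fry asks whether a list moved at all and not whether it moved more than the other genes), other forms of the signature (no fold minimum, day 0 genes only, a prior count of 0.5), and an adjusted p of 0.01 for the overlaps. Alternatives chosen after seeing the data were the removal of 3 EV libraries of the Ezh2 series (in each group the one furthest from the others, at 1.35, 1.57 and 1.62 times their distance), overlaps of genes off chromosomes 6 and 8, an offset by chromosome median, leaving out each library for the gene lists, and a joint fit of the WT libraries of both series. WT day 0 replicate 2 of the Ezh2 series (1.95) and WT day 1 replicate 3 of the Suz12 series (2.01) lay further from their groups than these, and amKR day 1 replicate 2 as far (1.57), and they were left out singly. No library was left out of the values reported.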

Results

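Messenger RNA was counted in 54 libraries of mouse embryonic stem cells, 3 for each of 3 lines on each of 3 days in 2 series. The study concerns PRC2, the complex that methylates histone H3 on lysine 27 and keeps developmental genes silent, of which Ezh2 (or its paralog Ezh1) is the enzyme and Suz12 and Eed are core subunits. Between 18318 and 20437 genes had a count in each library. Values below are mean ± SD of 3 libraries in CPM, and log2 changes carry their SE. In the Ezh2 series the libraries of a group spread more, with a common dispersion of 0.0192 against 0.00536 in the Suz12 series.

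The first question is which PRC2 genes each line expresses. Suz12 (ENSMUSG00000017548, chromosome 11) was low in EV of the Suz12 series on day 0, at 68.1 ± 4.97 against 439 ± 8.62 CPM (log2 change -2.69 ± 0.08, adjusted p 2.3e-36). Ezh2 (ENSMUSG00000029687, chromosome 6) was counted in EV of the Ezh2 series at 183 ± 16.9 against 88.3 ± 0.66 CPM in WT, although the labels give that line as lacking Ezh2, and counts near the 3′ end do not say which part of the gene was lost. Ezh1 (ENSMUSG00000006920, chromosome 11), lost in all 3 lines per the labels, stood at 9.29 ± 1.58 CPM in EV on day 0 and at 0.148 ± 0.257 CPM in WT. Eed (ENSMUSG00000030619, chromosome 7) was present in every group. Because EV of the Ezh2 series carried Ezh1 counts that WT and amKR almost lacked, comparisons with it set lines apart that differ in more than the added Ezh2, and they do not isolate the loss of the enzymes.

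**Figure D1:**
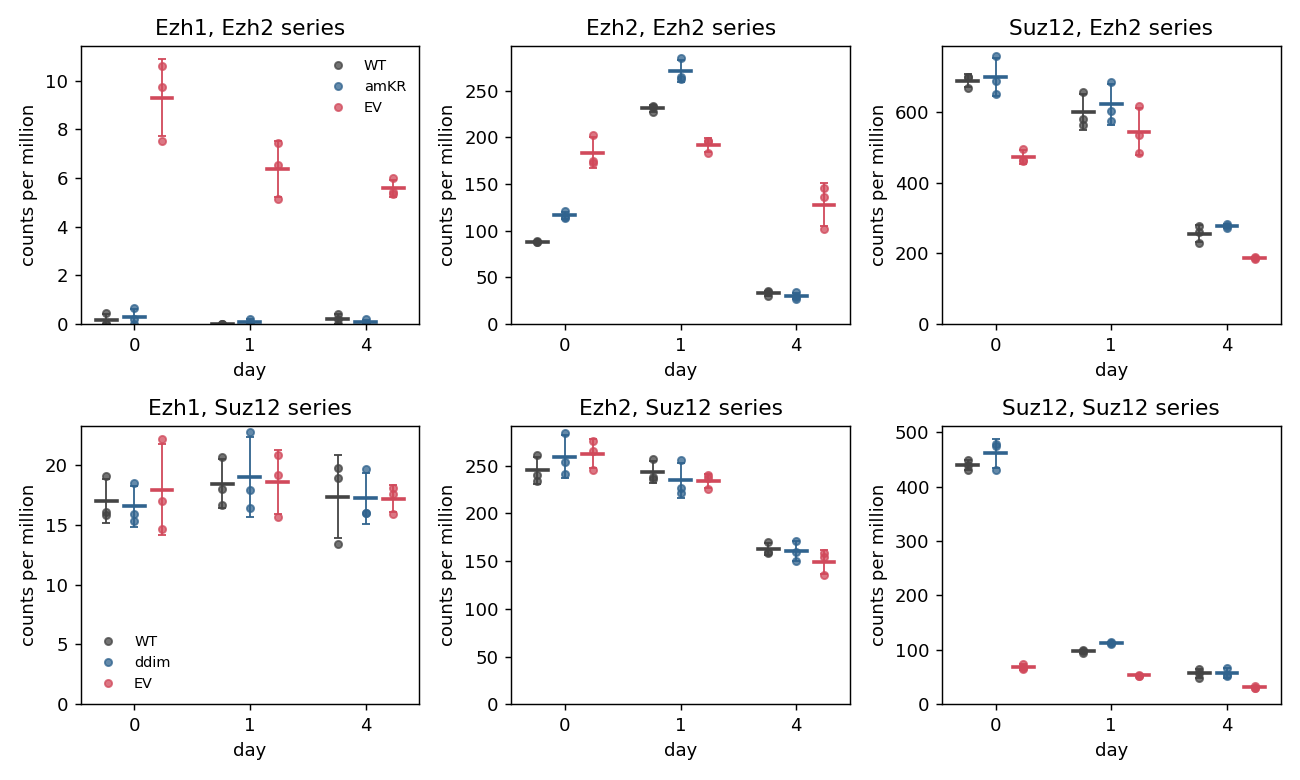
CPM of Ezh1, Ezh2 and Suz12 (vertical axes, from 0) in each line by day (horizontal axes), with the Ezh2 series above and the Suz12 series beneath. Points are libraries, short lines are group means and bars are the SD of 3 libraries, with Suz12 in EV of the Suz12 series at 68.1 ± 4.97 CPM on day 0 and Ezh1 in WT of the Ezh2 series at 0.148 ± 0.257 CPM.

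How cells with the restored wild-type Ezh2 leave the stem cell state was read from the WT time course. On day 1 the genes of early, formative development rose. Pou3f1, a transcription factor of the early epiblast, went to 80.6 ± 3.77 against 0.899 ± 0.378 CPM on day 0 (log2 change 6.44 ± 0.25, adjusted p 1.01e-19). The DNA methyltransferase Dnmt3b rose by 3.22 ± 0.11 and Tcf15, which primes pluripotent cells for differentiation, by 3.54 ± 0.13. The cell cycle gene Ccnd2 rose by 6.46. Klf4, a factor of the naive state, fell by 2.83 to 131 ± 11.3 CPM, the receptor gene Kit fell by 3.63 and Spic fell by 6.85. Formative and primed pluripotency rose as a list (11 of 15 genes higher and 1 lower, 11 and 1 adjusted over the list alone, adjusted p 4.17e-08). Naive pluripotency fell (4 of 25 genes higher and 19 lower, 4 and 19 adjusted over the list alone, adjusted p 4.86e-06). Hox genes, which set position along the body axis, fell as a list (1 of 31 genes higher and 15 lower, 1 and 15 adjusted over the list alone, adjusted p 0.00202), among them Hoxc10 by 3.99. Retinoic acid response genes went both ways on day 1: the receptor gene Rarg rose by 2.62 to 422 ± 51 CPM, while Tgm2, a transglutaminase that retinoic acid induces in many cells, fell by 4.26, and the list did not pass the test (adjusted p 0.685). Extraembryonic endoderm (adjusted p 0.0241) and trophectoderm (adjusted p 0.0352) rose with the preset correlation alone. So did mesoderm and primitive streak (adjusted p 0.0224) and germline genes (adjusted p 0.0203). With an estimated correlation the adjusted p was 0.0836 for extraembryonic endoderm and 0.1 for the others. Ezh2 rose by 1.39 (adjusted p 3.82e-12) and Eed by 0.67 (adjusted p 6.25e-05), and neither Suz12 (adjusted p 0.0943) nor Ezh1 (adjusted p 0.187) changed. edgeR called 6549 genes on day 1, 3146 higher and 3403 lower.

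By day 4 the retinoic acid response and extraembryonic endoderm lists were higher in the WT cells than on day 0. Cyp26b1, an enzyme that degrades retinoic acid, reached 360 ± 56.7 against 0.675 ± 0.219 CPM on day 0 (log2 change 9.00 ± 0.31, adjusted p 2.41e-19). Hoxb1, a hindbrain Hox gene and direct retinoic acid target, stood at 78.7 ± 6.41 CPM and Hoxa5 rose by 6.86. The basement membrane genes Col4a1 and Lamb1 rose by 7.40 and 7.64 to 1150 ± 84 CPM and 1420 ± 143 CPM. Acta2, a smooth muscle actin, stood at 818 ± 220 CPM with no count on day 0. Tfcp2l1, a factor of the naive state, fell by 5.14, the growth factor gene Fgf4 fell by 9.13 and Tdgf1, a Nodal co-receptor, fell by 8.74. The imprinted genes Peg3 and Cdkn1c rose by 5.59 and 7.33. Retinoic acid response rose as a list (19 higher and 3 lower of 24, 19 and 3 adjusted over the list alone, adjusted p 6.23e-10). Extraembryonic endoderm rose too (30 higher and 1 lower of 31, 30 and 1 adjusted over the list alone, adjusted p 1.14e-19). Further lists that rose were Hox genes (adjusted p 2.85e-06), bivalent developmental transcription factors (adjusted p 2.64e-10), fibroblast and feeder markers (adjusted p 1.42e-07) and trophectoderm (adjusted p 0.0135). The same held for neural differentiation (adjusted p 0.00373, adjusted p = 0.066 with an estimated correlation), cell cycle inhibitors and p53 targets (adjusted p 0.000144) and imprinted genes (adjusted p 0.00111). Naive pluripotency fell (0 higher and 23 lower of 25, 0 and 23 adjusted over the list alone, adjusted p 4.12e-19), as did general pluripotency (1 higher and 13 lower of 14, 1 and 13 adjusted over the list alone, adjusted p 2.09e-08). PRC2 subunits fell as a list (3 higher and 7 lower of 14, 3 and 7 adjusted over the list alone, adjusted p 0.0307, adjusted p = 0.0581 with an estimated correlation). Ezh2 fell by 1.41, Suz12 by 1.43 and Eed by 0.97, while Ezh1 stayed near the floor (adjusted p 0.821). The calls were 8036, of which 4164 were higher and 3872 lower.

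**Figure D2:**
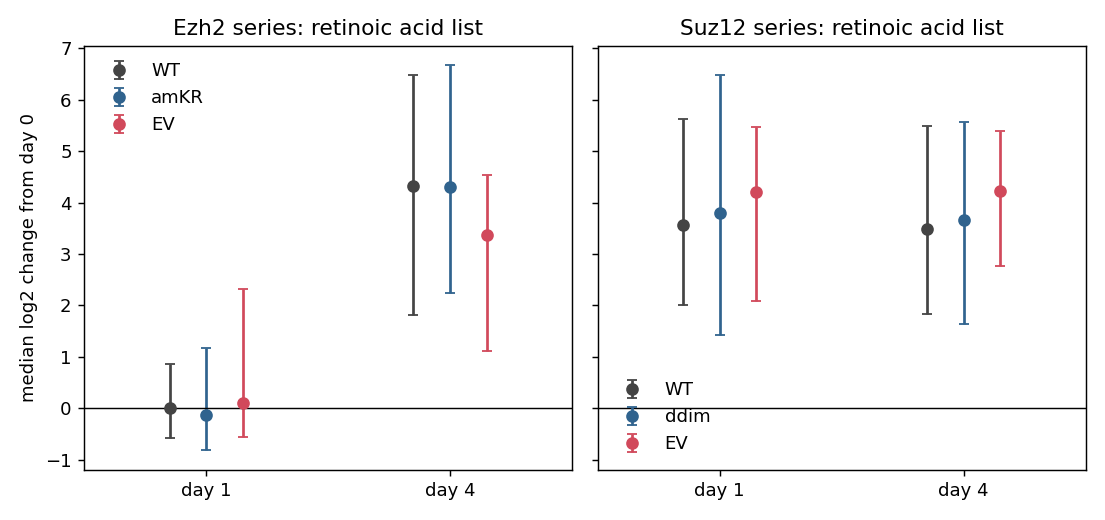
Median log2 change against day 0 (vertical axis) of the 24 tested genes of the retinoic acid response list in each line on days 1 and 4 (horizontal axis), with bars for the 95% interval of the median. On day 1 the median was 0.00 in WT of the Ezh2 series and 3.56 in WT of the Suz12 series, and on day 4 it was 4.32 and 3.49, while the 4.23 of EV of the Suz12 series on day 4 becomes 3.97 with 1 gene without counts placed at its bound.

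EV of the Ezh2 series, which its label gives as lacking both PRC2 enzymes, was compared with WT in undifferentiated cells on day 0. Bivalent developmental, germline and 2-cell-like genes were higher in EV. Hoxa10, a posterior Hox gene, stood at 23.5 ± 4.01 against 0.451 ± 0.00502 CPM in WT (log2 change 5.62 ± 0.43, adjusted p 1.46e-11), and Olig2, a factor of the neural lineage, at 11 ± 4.95 CPM with no count in WT. Sfmbt2, an imprinted gene needed in the placenta, rose by 3.20 ± 0.15 (adjusted p 4.64e-17), and Cdkn1c, an imprinted inhibitor of the cell cycle, by 3.94. Col4a1 rose by 2.93 ± 0.14, and Syce1, a part of the synaptonemal complex of meiosis, by 2.13 to 77.4 ± 6.96 CPM. The muscle enzyme gene Fbp2 rose by 4.83. Among the falls, the ETS factor gene Etv4 went from 19.2 ± 1.2 CPM to 1.83 ± 1.3 CPM (log2 change -3.37 ± 0.30), the RNA-binding protein gene Lin28a fell by 1.77 and Rarg by 1.74. Bivalent developmental transcription factors, which carry active and PRC2 marks together in stem cells, rose as a list (28 higher and 2 lower of 73, 30 and 2 adjusted over the list alone, adjusted p 1.11e-07). Hox genes (14 higher and 2 lower of 31, 15 and 3 adjusted over the list alone, adjusted p 0.00137) and germline genes (15 higher and 2 lower of 24, 17 and 3 adjusted over the list alone, adjusted p 3.33e-06) rose. Extraembryonic endoderm rose as well (11 higher and 3 lower of 31, 13 and 3 adjusted over the list alone, adjusted p 0.00187). All 11 tested genes of the 2-cell-like list, named for the early embryo stage at which they are active, were called higher (11 and 0 adjusted over the list alone, adjusted p 7.21e-10). Their median log2 change was 3.74 with genes that had no count in a group placed at the bound that 3 counts give. Neural differentiation (adjusted p 0.00515) and fibroblast and feeder markers (adjusted p 0.0174) rose with the preset correlation alone. With an estimated correlation they had adjusted p of 0.122 and 0.128. Housekeeping controls (adjusted p 0.123) and PRC2 subunits (adjusted p 0.572) did not move as lists, although Ezh2 rose by 1.05 ± 0.11 (adjusted p 6.81e-09), Eed rose by 0.71 (adjusted p 8.25e-05) and Suz12 fell by 0.54 (adjusted p 8.07e-05). Ezh1 was called higher (adjusted p 4.4e-08), and Hprt, a purine salvage enzyme gene, stood at 25.8 ± 6.08 against 0.301 ± 0.133 CPM. edgeR called 4123 genes, 2372 higher and 1751 lower.

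On day 1 the same comparison asks how EV and WT differ as they leave the stem cell state. Extraembryonic endoderm genes were higher in EV. Gata6 and Gata4, which drive primitive endoderm, stood at 66.2 ± 6.13 against 3.46 ± 1.08 CPM (log2 change 4.25 ± 0.26, adjusted p 2.37e-13) and 12.6 ± 2.3 against 0.509 ± 0.541 CPM (adjusted p 1.72e-10). Pdgfra, a receptor gene of the same lineage, stood at 24 ± 1.82 CPM in EV and 0.15 ± 0.26 CPM in WT, and Lamb1 rose by 2.87. Sfmbt2 rose by 3.67, Hoxa10 by 2.88 and Id2, an inhibitor of helix-loop-helix factors, by 2.29. The cystine transporter gene Slc7a11 fell by 6.17 from 29.8 ± 4.41 CPM to 0.393 ± 0.282 CPM (adjusted p 7.7e-15). Trib3 and Chac1, which are induced when amino acids run short or proteins misfold, fell by 4.16 and 4.28, and the stress gene Nupr1 by 4.01. The 2-cell-like genes had the smallest p (11 higher and 0 lower of 11, 11 and 0 adjusted over the list alone, adjusted p 8.08e-13), with a median log2 change of 4.01 when genes without a count in a group are placed at their bound. Extraembryonic endoderm was higher (18 higher and 1 lower of 31, 21 and 1 adjusted over the list alone, adjusted p 2.93e-12), as were bivalent developmental transcription factors (36 higher and 4 lower of 73, 39 and 5 adjusted over the list alone, adjusted p 1.23e-10). Germline genes (17 higher and 0 lower of 24, 20 and 0 adjusted over the list alone, adjusted p 6.73e-08) and Hox genes (15 higher and 0 lower of 31, 17 and 0 adjusted over the list alone, adjusted p 7.74e-08) were higher too. Formative and primed pluripotency (adjusted p 0.000291), trophectoderm (adjusted p 0.000474), and fibroblast and feeder markers (adjusted p 0.00327) passed in the same direction. So did cell cycle inhibitors and p53 targets (adjusted p 0.00463), retinoic acid response (adjusted p 0.0168), imprinted genes (adjusted p 0.00389, adjusted p = 0.0653 with an estimated correlation) and neural differentiation (adjusted p 0.0161, adjusted p = 0.119 with an estimated correlation). Mesoderm and primitive streak (adjusted p 0.0254, adjusted p = 0.106 with an estimated correlation) was higher as well, a call that ended without WT replicate 2. Ezh2 (adjusted p 0.0645), Suz12 (adjusted p 0.337) and Eed (adjusted p 0.766) did not change, and Ezh1 stood at 6.37 ± 1.15 CPM in EV with no count in WT. The calls were 2937, 1861 higher and 1076 lower.

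On day 4 general pluripotency genes were lower in EV than in WT, and bivalent developmental transcription factors were higher. Pitx1, a homeobox gene of hindlimb and face, stood at 36.2 ± 7.62 against 1.6 ± 1.44 CPM (log2 change 4.49, adjusted p 4.12e-10), and Six3, a forebrain homeobox gene, rose by 4.13. Cdkn1a, the p53 target that halts the cell cycle, rose by 1.35 to 651 ± 40.1 CPM (adjusted p 2.64e-11), and Perp, another p53 target, by 1.56. Ddr2, a collagen receptor gene, fell by 5.21 from 93.7 ± 7.26 CPM to 2.5 ± 0.417 CPM (adjusted p 1.11e-19). Slc7a11 fell by 5.39, Nupr1 fell by 4.94 and Trib3 fell by 4.37. The imprinted gene Mest fell by 2.01, and Hoxb1 fell by 1.87 to 21.4 ± 3.38 CPM (adjusted p 8.3e-09). General pluripotency fell as a list (1 higher and 11 lower of 14, 1 and 12 adjusted over the list alone, adjusted p 1.6e-08). Bivalent developmental transcription factors rose (33 higher and 10 lower of 73, 37 and 14 adjusted over the list alone, adjusted p 5.95e-06), and so did trophectoderm (11 higher and 3 lower of 20, 11 and 3 adjusted over the list alone, adjusted p 4.65e-05). Cell cycle inhibitors and p53 targets rose (11 higher and 2 lower of 18, 12 and 2 adjusted over the list alone, adjusted p 3.09e-07). Ezh2 rose by 1.95 ± 0.12 (adjusted p 1.75e-14) and Suz12 fell by 0.45 (adjusted p 0.00126). Eed rose by 0.44 (adjusted p 0.0175), a call that ended without EV replicate 1 or WT replicate 2 or 3, and Ezh1 was called higher (adjusted p 1.33e-06). The calls were 2510, 1355 higher and 1155 lower, and 1515 with only the libraries compared in the fit.

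**Figure D3:**
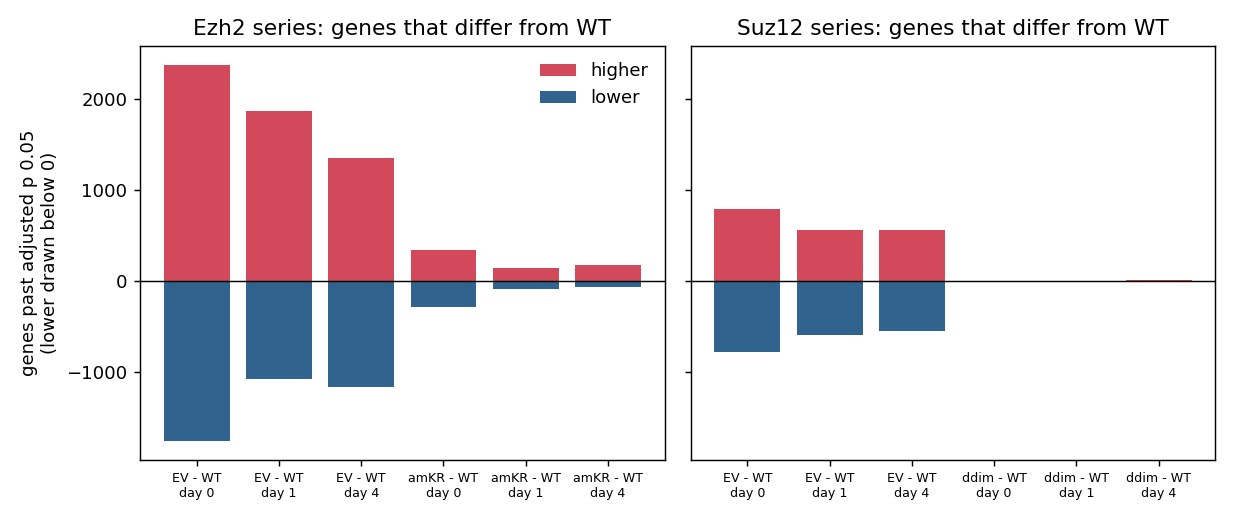
Number of genes called higher than WT (upward bars) and lower than WT (downward bars), in genes on the vertical axes, for EV and for the mutant on each day (horizontal axes) in both series. Calls against WT on days 0, 1 and 4 were 4123, 2937 and 2510 for EV and 631, 230 and 241 for amKR in the Ezh2 series, and 1566, 1143 and 1104 for EV and 0, 9 and 22 for ddim in the Suz12 series.

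amKR was set against WT in undifferentiated cells on day 0 to ask about the automethylated lysines of Ezh2. These are single lines that differ along chromosomes 6 and 8, so calls on any day may come from the line, not the lysines. Fewer genes were called than for EV. Tmem47, a membrane protein gene of cell junctions, rose from 8.73 ± 1.92 CPM to 34 ± 6.19 CPM (log2 change 1.96 ± 0.21, adjusted p 1.36e-06), and Tbl1x, a subunit of a histone deacetylase corepressor complex, from 19.4 ± 1.88 CPM to 61.7 ± 6.22 CPM (adjusted p 2.13e-09). Tdh, a threonine dehydrogenase that feeds stem cell metabolism, rose by 0.59 (adjusted p 0.00296) and the B-cell and neural factor gene Ebf1 by 1.01 (adjusted p 0.00117). Etv4 fell by 1.47 (adjusted p 0.000531), as did the early response gene Fosb by 1.42 (adjusted p 7.6e-05) and the imprinted gene Peg10 by 0.69 (adjusted p 0.000368). Naive pluripotency was the only list past the threshold (5 higher and 0 lower of 25, 9 and 0 adjusted over the list alone, adjusted p 0.000788, adjusted p = 0.128 with an estimated correlation). Ezh2 was higher by 0.40 (adjusted p 0.0303), a call that ended whichever library was left out, and Eed by 0.53 (adjusted p 0.015), a call that ended without amKR replicate 1 or 3 or WT replicate 2. Suz12 (adjusted p 0.938) and Ezh1 (adjusted p 0.715) did not change. The 631 calls, 344 higher and 287 lower, went down to 219, 282 and 182 without amKR replicates 1, 2 and 3 and to 315 and 151 without WT replicates 1 and 2, and up to 1807 with only the libraries compared in the fit. With an offset by chromosome median 300 were higher and 244 lower.

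On day 1 amKR was again compared with WT to ask about the same lysines during differentiation. Gata6 rose from 3.46 ± 1.08 CPM to 21.2 ± 5.27 CPM (log2 change 2.61 ± 0.28, adjusted p 2.22e-06), and Tmem47 by 2.55 and Tbl1x by 1.67 (adjusted p 1.43e-07 and 7.54e-09). The endothelin gene Edn2 rose by 2.78 (adjusted p 0.00118), Wt1, a factor of kidney and gonad development, by 1.27 (adjusted p 0.00341), and Grb10, an imprinted inhibitor of growth signalling, by 1.33 ± 0.17 (adjusted p 1.15e-05). Peg10 fell by 0.70 (adjusted p 4.66e-05) and the muscle factor gene Mef2b by 1.10 (adjusted p 0.00279). 2-cell-like genes rose as a list (1 higher and 0 lower of 11, 4 and 0 adjusted over the list alone, adjusted p 3.16e-05), with a median log2 change of 1.70 when genes without a count in a group are placed at their bound. Germline genes rose with the preset correlation alone (2 higher and 0 lower of 24, 7 and 0 adjusted over the list alone, adjusted p 0.0024, adjusted p = 0.063 with an estimated correlation). The same was true of cell cycle inhibitors and p53 targets (2 higher and 0 lower of 18, 2 and 0 adjusted over the list alone, adjusted p 0.0279, adjusted p = 0.126 with an estimated correlation), a call that ended without amKR replicate 2 or WT replicate 1 or 3. None of Ezh1, Ezh2, Suz12 and Eed changed (adjusted p 0.574, 0.246, 0.836 and 0.235). The 230 calls, 148 higher and 82 lower, went down to 75 without amKR replicate 1 and to 55, 76 and 91 without WT replicates 1, 2 and 3, and up to 671 with only the libraries compared in the fit, 389 with DESeq2 and 501 with no filter on low counts. With an offset by chromosome median 147 were higher and 59 lower.

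On day 4 extraembryonic endoderm genes were higher in amKR than in WT. In a fit of these libraries alone a split mixing the lines gave 425 calls and the real one 233. Some calls may reflect differences within lines. Afp, the fetal serum protein of yolk sac and liver, stood at 13.1 ± 2.99 against 1.18 ± 0.701 CPM (log2 change 3.44 ± 0.48, adjusted p 0.000138). Apob, the lipoprotein gene of the same tissues, rose by 2.77 ± 0.33 to 83.3 ± 14.9 CPM (adjusted p 3.19e-05), and Ttr, a carrier of thyroid hormone and retinol, by 1.61 to 71.6 ± 2.69 CPM (adjusted p 9.79e-05). Tmprss2, an epithelial protease gene, rose by 2.49 (adjusted p 4.77e-06), Tdh by 1.57 (adjusted p 8.45e-09) and Grb10 by 1.15 (adjusted p 5.32e-06). Ebf1, which was higher on days 0 and 1, fell by 1.40 to 11 ± 2.83 CPM (adjusted p 9.55e-05). Hsf2bp, a gene of meiotic recombination, fell by 1.49, Foxc2, a factor of mesenchyme, by 1.24, Sox2 by 0.98 and the cartilage factor gene Sox9 by 0.70 (adjusted p 6.55e-08, 0.00306, 0.00448 and 0.0032). Extraembryonic endoderm rose as a list (10 higher and 0 lower of 31, 15 and 0 adjusted over the list alone, adjusted p 5.25e-10), as did trophectoderm (2 higher and 0 lower of 20, 5 and 0 adjusted over the list alone, adjusted p 0.00783). In the list test 2-cell-like genes came out higher (0 higher and 0 lower of 11, 1 and 0 adjusted over the list alone, adjusted p 3.22e-06) and retinoic acid response lower (0 higher and 0 lower of 24, 0 and 5 adjusted over the list alone, adjusted p 0.00883), although no member was called over all genes. Their median log2 changes were 1.32, with a gene without counts in a group at its bound, and -0.31. With the preset correlation alone, neural differentiation (adjusted p 0.00842), general pluripotency (adjusted p 0.0224) and Hox genes (adjusted p 0.0242) fell. Likewise, cell cycle inhibitors and p53 targets (adjusted p 0.0232) and imprinted genes (adjusted p 0.0242) rose. With an estimated correlation these had adjusted p of 0.0958, 0.232, 0.0577, 0.0958 and 0.162 in turn. Of these, WT replicate 3 decided the neural, pluripotency, Hox and cell cycle calls, WT replicate 2 the pluripotency and imprinted ones, WT replicate 1 the Hox one, amKR replicate 1 the Hox and imprinted ones and amKR replicate 2 the cell cycle one. Ezh1, Ezh2, Suz12 and Eed did not change (adjusted p 0.769, 0.701, 0.694 and 0.279). The 241 calls, 172 higher and 69 lower, went down to 109 and 84 without amKR replicates 2 and 3 and to 131 and 94 without WT replicates 2 and 3. With an offset by chromosome median 155 were higher and 44 lower.

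How far amKR departs from EV was asked by comparing them on each day. Hox, germline, 2-cell-like and bivalent genes, which were higher in EV than in WT on day 0, were lower in amKR than in EV. On day 0 Hoxa10 stood at 0.432 ± 0.748 against 23.5 ± 4.01 CPM in EV (adjusted p 2.28e-11), and Ap3b2, a vesicle adaptor gene of neurons, rose by 2.73. On day 1 Gata4 fell by 4.69 (adjusted p 2.87e-10) and Pdgfra by 4.66, while Slc7a11 stood at 24.8 ± 1.04 against 0.393 ± 0.282 CPM in EV (adjusted p 6.82e-14). On day 4 Nupr1 stood at 61.7 ± 7.19 against 2.49 ± 0.542 CPM and Ddr2 at 46.9 ± 7.99 against 2.5 ± 0.417 CPM in EV, and Pitx1 fell by 4.49 and Six3 fell by 3.75. 2-cell-like genes (0 higher and 11 lower of 11, 0 and 11 adjusted over the list alone, adjusted p 1.43e-12) and bivalent developmental transcription factors (0 higher and 26 lower of 73, 0 and 29 adjusted over the list alone, adjusted p 6.46e-11) were lower on day 0. Germline genes (1 higher and 15 lower of 24, 1 and 18 adjusted over the list alone, adjusted p 4.67e-10) and Hox genes (0 higher and 15 lower of 31, 0 and 18 adjusted over the list alone, adjusted p 2.13e-08) were lower too. On day 1 extraembryonic endoderm gave the smallest p (1 higher and 20 lower of 31, 2 and 21 adjusted over the list alone, adjusted p 7.52e-14). On day 4 that list was higher in amKR (14 higher and 3 lower of 31, 14 and 3 adjusted over the list alone, adjusted p 0.000512), and so was general pluripotency (8 higher and 0 lower of 14, 8 and 0 adjusted over the list alone, adjusted p 2.67e-07). Ezh2 differed from EV by -0.65, 0.50 and -2.09 on days 0, 1 and 4 (adjusted p 3.72e-05, 0.000883 and 4.23e-15), the day 1 call ending with the chromosome offset. Suz12 differed by 0.56, 0.19 and 0.57 (adjusted p 8.08e-05, 0.21 and 0.000111), and Eed did not differ (adjusted p 0.379, 0.283 and 0.718). Ezh1 was lower than in EV on every day (adjusted p 1.81e-07, 4.82e-07 and 5.09e-07). The calls were 2463, 2077 and 1524, of which 901, 753 and 743 were higher in amKR.

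Whether these effects change with differentiation was tested as the difference between the day 4 and day 0 effects. For EV, Ddr2 (log2 difference -5.36), the neural factor gene Sox11 (-4.90) and the amino acid enzyme genes Pck2 (-3.02) and Bcat1 (-2.81) moved downward against WT, and the cadherin gene Cdh1 (1.59) and the growth factor gene Hbegf (2.25) upward. Germline genes (0 higher and 12 lower of 24, 0 and 14 adjusted over the list alone, adjusted p 7.94e-09) and 2-cell-like genes (0 higher and 6 lower of 11, 0 and 10 adjusted over the list alone, adjusted p 4.29e-08) had a smaller or more negative EV effect on day 4. The same was found for extraembryonic endoderm (4 higher and 11 lower of 31, 4 and 12 adjusted over the list alone, adjusted p 0.00233). The Ezh2 effect was larger by 0.89 (adjusted p 0.00014), and those of Ezh1, Suz12 and Eed did not differ (adjusted p 0.678, 0.739 and 0.401). The EV effect differed in 1751 genes, 715 upward and 1036 downward. For amKR, Ebf1 (-2.41 ± 0.27, adjusted p 6.86e-06) and Hsf2bp (-1.19, adjusted p 0.00161) moved downward, and the metallothionein gene Mt2 (1.25, adjusted p 6.57e-05) and the chloride channel gene Clcn5 (1.13, adjusted p 0.00608) upward. The extraembryonic endoderm list came out higher in the list test, although no member was called over all genes (0 higher and 0 lower of 31, 3 and 0 adjusted over the list alone, adjusted p 9.18e-08), while Ezh1, Ezh2, Suz12 and Eed did not differ (adjusted p 0.77, 0.222, 0.888 and 0.806). The amKR effect differed in 22 genes, 17 upward and 5 downward, and in 12, 11, 13, 12 and 13 without amKR day 0 replicates 1 and 3 and day 4 replicates 1, 2 and 3, and in 9 and 8 without WT replicate 1 of day 0 and of day 4.

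The WT line of the Suz12 series was followed over the same days. Retinoic acid targets and endoderm genes were already high on day 1. Hoxb1 stood at 339 ± 15.4 against 0.267 ± 0.0016 CPM on day 0, and Stra8, the retinoic acid target that starts meiosis in germ cells, rose by 8.36 ± 0.15 to 626 ± 60.3 CPM (adjusted p 9.84e-48). The endoderm adaptor gene Dab2 rose by 8.19 and Gata6 by 5.44. Esrrb, a nuclear receptor of the naive state, fell by 5.10, Sox2 by 3.97 and the epiblast factor gene Otx2 by 3.59. Zscan4c, a gene of the 2-cell stage with near-identical neighbours whose reads are hard to separate, rose by 4.25. On day 4 Acta2 rose by 12.32 ± 0.14 to 4250 ± 260 CPM, and the collagen gene Col3a1 stood at 458 ± 4.27 CPM against 0.0892 ± 0.155 CPM. Nr2f2, a nuclear receptor gene of mesenchyme, rose by 6.66, Gata4 by 6.67 and the imprinted gene Dlk1 by 7.97. Nanog fell by 10.54, Sox2 by 6.92 and the germ cell gene Dazl by 6.94. Retinoic acid response (22 higher and 1 lower of 24, 22 and 2 adjusted over the list alone, adjusted p 3.91e-12) and extraembryonic endoderm (28 higher and 1 lower of 31, 28 and 1 adjusted over the list alone, adjusted p 6.29e-16) rose by day 1. Hox genes rose (24 higher and 4 lower of 32, 25 and 4 adjusted over the list alone, adjusted p 3.01e-08) and naive pluripotency fell (0 higher and 25 lower of 25, 0 and 25 adjusted over the list alone, adjusted p 6.15e-17). On day 4 fibroblast and feeder markers (16 higher and 0 lower of 19, 16 and 0 adjusted over the list alone, adjusted p 8.75e-09) were also higher. Germline genes (2 higher and 15 lower of 23, 2 and 15 adjusted over the list alone, adjusted p 0.000299) and general pluripotency (0 higher and 14 lower of 14, 0 and 14 adjusted over the list alone, adjusted p 1.88e-10) were lower. Suz12 fell by 2.18 on day 1 and by 2.95 on day 4, and Eed by 1.27 and 1.75. Ezh2 did not change on day 1 (adjusted p 0.95) and fell by 0.59 on day 4 (adjusted p 3.16e-10), and Ezh1 did not change (adjusted p 0.562 and 0.891). The calls were 8937 on day 1, 4732 higher, and 10625 on day 4, 5357 higher.

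Suz12 series EV was set against WT on day 0. Calls on any day may come from the single lines. Imprinted, bivalent, Hox and 2-cell-like genes were lower in EV. The maternally expressed RNA Meg3 fell by 3.59 from 118 ± 9.57 CPM to 9.73 ± 1.99 CPM (adjusted p 3.39e-14), and its neighbours in the same imprinted cluster, Rian and Mirg, fell by 3.09 and 4.25. The neural factor gene Sox3 fell by 3.09 and the placental factor gene Ascl2 fell by 2.21. Rhox5, an X-linked homeobox gene of placenta and testis, rose by 2.11 ± 0.10 to 458 ± 71.6 CPM (adjusted p 6.98e-17). The citrate transporter gene Slc13a5 rose by 2.42, and Olig2 by 2.03 to 72.3 ± 5.29 CPM (adjusted p 2.8e-14). Bivalent developmental transcription factors fell as a list (3 higher and 23 lower of 82, 3 and 31 adjusted over the list alone, adjusted p 6.4e-10), and so did Hox genes (0 higher and 11 lower of 32, 0 and 11 adjusted over the list alone, adjusted p 2.62e-07). Imprinted genes (4 higher and 13 lower of 31, 4 and 15 adjusted over the list alone, adjusted p 4.46e-06) and 2-cell-like genes (0 higher and 5 lower of 11, 0 and 9 adjusted over the list alone, adjusted p 4.46e-06) fell. With genes that had no count in a group at their bound, the median log2 changes of these lists were -0.97, -0.12, -0.30 and -1.28. Extraembryonic endoderm fell with the preset correlation alone (adjusted p 0.0152, adjusted p = 0.132 with an estimated correlation), a call that ended without WT replicate 3. Ezh1, Ezh2 and Eed did not change (adjusted p 0.851, 0.439 and 0.424). The calls were 1566, 790 higher and 776 lower.

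On day 1 general pluripotency genes were higher in EV than WT, and imprinted and endoderm genes lower. Nanog, a core pluripotency factor, stood at 32.8 ± 2.3 against 8.78 ± 2.31 CPM (log2 change 1.91, adjusted p 4.22e-05), Tdgf1 at 26.9 ± 0.992 against 6.59 ± 1.38 CPM (log2 change 2.02 ± 0.15, adjusted p 6.96e-16) and Sox2 at 94.4 ± 6.46 against 43.6 ± 2.43 CPM (adjusted p 4.25e-15). Mest, a paternally expressed gene of growth, fell by 2.70 (adjusted p 2.67e-22), Meg3 by 2.78 and the maternally expressed RNA H19 by 2.30. Zscan4c fell by 2.25, with the same doubt about its neighbours, and Col4a1 by 0.54 and Gata6 by 0.52. General pluripotency rose as a list (5 higher and 1 lower of 14, 12 and 1 adjusted over the list alone, adjusted p 1.47e-05). 2-cell-like genes (0 higher and 9 lower of 11, 0 and 11 adjusted over the list alone, adjusted p 3.45e-13) and imprinted genes (2 higher and 16 lower of 31, 5 and 19 adjusted over the list alone, adjusted p 5.85e-09) fell. Extraembryonic endoderm fell (0 higher and 15 lower of 31, 0 and 20 adjusted over the list alone, adjusted p 6.62e-05), with trophectoderm (1 higher and 7 lower of 21, 3 and 12 adjusted over the list alone, adjusted p 0.00492). Suz12 fell by 0.88 (adjusted p 2.6e-11), and Ezh1, Ezh2 and Eed did not change (adjusted p 0.987, 0.702 and 0.0523). The 1143 calls, 558 higher and 585 lower, went down to 721 and 759 without EV replicates 2 and 3 and to 687 without WT replicate 3, and to 625 with only the libraries compared in the fit.

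On day 4 bivalent developmental transcription factors were higher in EV of the Suz12 series than in WT, and trophectoderm and imprinted genes were lower. Isg15, an interferon-induced ubiquitin-like protein, rose by 2.76 ± 0.24 to 29.3 ± 4.13 CPM (adjusted p 1.46e-13), and Usp18, the protease that removes it, by 2.32. Cyp26b1 fell by 1.90 from 240 ± 28.5 CPM to 64.5 ± 25.6 CPM (adjusted p 1.51e-07) and Cyp26a1 by 1.12 (adjusted p 2.99e-13). Zic1, a factor of the neural plate, rose by 2.18, Sox2 by 1.81 and Asb4, an imprinted gene of the placenta, by 2.41 (adjusted p 2.83e-21). Meg3 fell by 4.21, H19 by 2.33 and Mest by 2.26, while the imprinted receptor gene Igf2r rose by 1.01. Bivalent developmental transcription factors rose (12 higher and 3 lower of 82, 18 and 3 adjusted over the list alone, adjusted p 0.000565). Trophectoderm (2 higher and 10 lower of 21, 4 and 11 adjusted over the list alone, adjusted p 0.00034) and imprinted genes (8 higher and 14 lower of 31, 9 and 16 adjusted over the list alone, adjusted p 0.00444) fell. Suz12 fell by 0.85 (adjusted p 5.71e-09), and Ezh1, Ezh2 and Eed did not change (adjusted p 0.993, 0.385 and 0.598). The 1104 calls, 556 higher and 548 lower, went down to 707 without EV replicate 1 and to 656 without WT replicate 2, and up to 1857 with only the libraries compared in the fit.

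ddim was set against WT, also as single lines, to ask about dimerization of the complex. On day 0 no gene was called by edgeR (525 genes at an unadjusted p under 0.05, lowest adjusted p 0.358) or by DESeq2 (0 genes), no list passed the test, and leaving out ddim replicate 2 gave 1 call. Suz12 stood at 461 ± 26.9 against 439 ± 8.62 CPM in WT, and Suz12, Ezh1, Ezh2 and Eed had an adjusted p of 1. On day 1 edgeR called 9 genes. Ccdc8, a gene of growth and microtubule upkeep, rose by 0.77, Irak2, a kinase of innate immune signalling, by 0.51, Nr2f2 by 0.48 and Ifitm3, a membrane protein that restricts viruses, by 0.40 (adjusted p 0.00173, 0.0104, 0.00328 and 0.00476). Taf13, a general transcription factor gene, fell by 0.81, the ubiquitin ligase gene Dcaf1 by 0.60, the ETS factor gene Etv5 by 0.46, Gna13, a G protein gene, by 0.45 and the linker histone gene H1fx by 0.40. The 9 calls became 0 without WT replicate 3, 90 and 17 without WT replicates 1 and 2, and 5 and 1 without ddim replicates 2 and 3, and they became 0 with only the libraries compared in the fit and 61 with no filter on low counts. No list passed on day 1, and Ezh1, Ezh2, Suz12 and Eed did not change (adjusted p 0.963, 0.841, 0.365 and 0.434).

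On day 4 some Hox genes were slightly higher in ddim than in WT. Hoxa5 rose from 123 ± 13.4 CPM to 182 ± 10.9 CPM (log2 change 0.57 ± 0.08, adjusted p 2.1e-05), Dhrs3, an enzyme that lowers retinoic acid levels, by 0.59 ± 0.10 (adjusted p 0.000909) and the matrix protein gene Ecm1 by 0.45 ± 0.06 (adjusted p 2.19e-05). Rbbp7, a histone-binding subunit of PRC2 and of deacetylase complexes, fell by 0.38 from 802 ± 4.57 CPM to 616 ± 33.3 CPM (adjusted p 0.000909). Hox genes rose (3 higher and 0 lower of 32, 5 and 0 adjusted over the list alone, adjusted p 0.00299), a call that ended without WT replicate 2 or ddim replicate 1. Extraembryonic endoderm fell (0 higher and 1 lower of 31, 0 and 5 adjusted over the list alone, adjusted p 0.000503), a call that ended without ddim replicate 1. With the preset correlation alone, retinoic acid response came out higher (adjusted p 0.0423). Likewise, general pluripotency (adjusted p 0.0152), formative and primed pluripotency (adjusted p 0.0423) and housekeeping controls (adjusted p 0.0477) came out lower. With an estimated correlation these lists had adjusted p of 0.203, 0.167, 0.354 and 0.203 in turn. These calls all ended without WT replicate 2 or ddim replicate 2, the retinoic acid one also without WT replicate 1 or ddim replicate 1, and the formative and housekeeping ones also without WT replicate 3 or ddim replicate 1. Ezh1, Ezh2, Suz12 and Eed did not change (adjusted p 1, 0.97, 0.984 and 0.933). The 22 calls, 12 higher and 10 lower, went down to 11, 10 and 11 without WT replicates 1, 2 and 3 and to 12, 11 and 9 without ddim replicates 1, 2 and 3. They went up to 187, 110 higher and 77 lower, with only the libraries compared in the fit, and to 48 with no filter on low counts.

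How far ddim departs from EV was asked by comparing them on each day. Suz12 was higher by 2.76, 1.09 and 0.87 on days 0, 1 and 4 (adjusted p 4.93e-37, 2.91e-15 and 1.64e-09), and so was Meg3, by 3.85, 3.20 and 4.77. Sox3 stood at 18 ± 2.59 against 1.97 ± 1.57 CPM in EV and Slc13a5 at 7.16 ± 0.568 against 64.2 ± 8.59 CPM on day 0. On day 1 Mest rose by 2.74 and Nanog fell by 2.39 to 6.25 ± 0.545 CPM. On day 4 Cyp26b1 rose by 2.44 and H19 by 2.38, and Isg15 fell by 2.82 to 4.12 ± 0.28 CPM. 2-cell-like genes rose on days 0 (9 higher and 0 lower of 11, 10 and 0 adjusted over the list alone, adjusted p 3.58e-08) and 1 (10 higher and 0 lower of 11, 11 and 0 adjusted over the list alone, adjusted p 2.99e-17). Imprinted genes rose on day 1 (15 higher and 3 lower of 31, 18 and 3 adjusted over the list alone, adjusted p 1.12e-09). Bivalent developmental transcription factors rose on day 0 (27 higher and 4 lower of 82, 33 and 7 adjusted over the list alone, adjusted p 4.99e-08) and fell on day 4 (6 higher and 23 lower of 82, 7 and 29 adjusted over the list alone, adjusted p 0.000213). Ezh1, Ezh2 and Eed did not differ on day 0 (adjusted p 0.758, 0.945 and 0.356), day 1 (adjusted p 0.956, 1 and 0.81) or day 4 (adjusted p 1, 0.441 and 0.792). The calls were 1687, 907 and 1646, of which 840, 483 and 795 were higher in ddim. The 907 of day 1 went down to 589, 604 and 580 without EV replicates 1, 2 and 3 and to 576 without ddim replicate 2, and the 1646 of day 4 to 1041 without ddim replicate 2. With only the libraries compared in the fit day 1 gave 1362.

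The difference between the day 4 and day 0 effects was tested in the Suz12 series as well. For EV, Suz12 itself moved by 1.84 (adjusted p 2.39e-16), as its level in WT fell with time. Dlk1 (3.76), the Wnt receptor gene Fzd2 (2.06), Sox2 (1.67) and the lipid carrier gene Apoe (1.09) moved upward, and Rhox5 (-1.81) and the intermediate filament gene Vim (-0.90) downward. Bivalent developmental transcription factors moved upward (25 higher and 1 lower of 82, 41 and 2 adjusted over the list alone, adjusted p 3.28e-13). Hox genes (9 higher and 0 lower of 32, 10 and 0 adjusted over the list alone, adjusted p 6.21e-06) and 2-cell-like genes (3 higher and 0 lower of 11, 6 and 0 adjusted over the list alone, adjusted p 4.04e-05) did so too. The effects on Ezh1, Ezh2 and Eed did not differ (adjusted p 0.903, 0.221 and 1). The EV effect differed in 998 genes, 509 upward and 489 downward. The ddim effect differed in 0 genes by edgeR (753 at an unadjusted p under 0.05, lowest adjusted p 0.777) and in 0 by DESeq2, Ezh1, Ezh2, Suz12 and Eed among them (adjusted p 1, 0.979, 1 and 1). Hox genes came out higher in the list test, although no member was called (0 higher and 0 lower of 32, 0 and 0 adjusted over the list alone, adjusted p 0.000343).

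How far amKR and EV calls overlap was asked within the Ezh2 series. Of the genes called in amKR on day 0, 253 of 344 higher and 186 of 287 lower were called the same way in EV, where 57.9 and 35.7 would be shared by chance. On day 1 this was 108 of 148 and 47 of 82 (19.6 and 6.26 by chance), and on day 4 it was 74 of 172 and 64 of 69 (16.5 and 5.66 by chance). The shared WT libraries raise the overlap. The 20 simulations with amKR effects on random genes keep that control. They gave fewer amKR calls than the data (183 higher and 100 lower on day 0). Shared calls then made up 13.7% of the higher and 16.5% of the lower amKR calls on day 0, 9.46% and 12.8% on day 1, and 8.42% and 14.9% on day 4, against 73.5% and 64.8%, 73% and 57.3%, and 43% and 92.8% in the data. Over all genes the correlation of the log2 changes, 0.504, 0.532 and 0.519, was close to the 0.5, 0.486 and 0.499 that the shared control alone gives in simulations without any effect, while their covariance was 0.334, 0.353 and 0.222 against 0.108, 0.107 and 0.096. Of the lower amKR calls 101, 36 and 28 lie on chromosomes 6 and 8, which hold 10.4% of the genes and carry lower counts in both lines than in WT. On the other chromosomes 242 of 327 higher and 112 of 186 lower amKR calls were shared on day 0 (57.1 and 20.8 by chance), 102 of 140 and 21 of 46 on day 1 (19.2 and 2.86 by chance), and 68 of 157 and 36 of 41 on day 4 (15.9 and 2.79 by chance). On day 4, 18 of the 172 genes higher in amKR were called lower in EV. Genes called the same way in ddim and EV of the Suz12 series numbered at most 3 in either direction on any day, and 6 of the 12 genes higher in ddim on day 4 were called lower in EV.

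Whether the series share genes was asked by comparing the EV calls and by the signatures. The 127 tested genes called higher by at least 1 on the log2 scale in EV of the Suz12 series on day 0 were higher in EV of the Ezh2 series by a mean of 1.11 and in amKR by 0.163. On days 1 and 4 the means were 0.778 and 0.305 in EV and 0.174 and 0.027 in amKR. Without the minimum of 1 the means on days 0, 1 and 4 were 0.406, 0.381 and 0.164 in EV, and on days 0 and 1 they were 0.042 and 0.098 in amKR. The amKR mean on day 4 was -0.006 without amKR replicate 3, 0.057 without amKR replicate 2 and 0.006 without WT replicate 2, and 0.126 with the genes of day 0, so its sign is not settled. The 1184 genes from EV of the Ezh2 series differed by -0.051 in EV and 0.001 in ddim of the Suz12 series on day 0. Exact permutation tests of 3 against 3 libraries cannot go below 0.1, the value reached in the Ezh2 series by EV on every day and by amKR on days 0 and 1, and in the Suz12 series by EV on days 0 and 4 and by ddim on day 1. There the differences were as small as -0.051, 0.06 and 0.021, so reaching 0.1 says little. amKR on day 4 gave 0.5. EV calls shared between series on day 0 were 272 higher (135 by chance) and 135 lower (92.4 by chance), beside 181 and 79 called the opposite way (126 and 98.8 by chance). On day 1 they were 161 and 46 (74 and 41.7 by chance, p 0.46 for the lower genes), beside 153 and 43 the opposite way (73.3 and 42.1 by chance). On day 4 they were 101 and 56 (51.1 and 44.4 by chance, p 0.0655 for the lower genes), beside 138 and 64 the opposite way (52.1 and 43.5 by chance). Genes higher in EV of the Ezh2 series and lower in that of the Suz12 series thus also exceeded chance on each day, and on day 4 they outnumbered those higher in both. Over all genes tested in both series the EV log2 changes had correlations of -0.055, -0.024 and 0.001 on days 0, 1 and 4. 12 genes were called the same way in EV in both series on all 3 days. Higher were Igf2r, the RNA-binding protein gene Igf2bp2, the X-linked homeobox genes Rhox5 and Rhox13, Klhl13, Rpl39l and AI662270, and lower were Meg3, Mirg, Rian, Mest and the myosin gene Myh9. Klhl13, Myh9, Igf2bp2, Rpl39l and AI662270 were named because they meet this rule, after their values were seen.

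**Figure D4:**
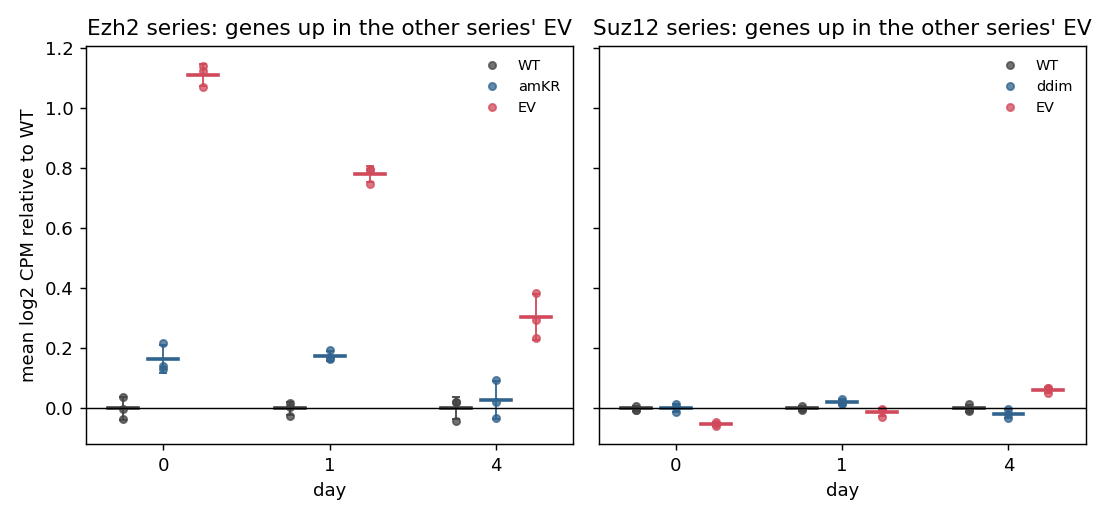
Mean log2 CPM, relative to WT, of the genes called higher in EV of the other series (vertical axis) in each line by day (horizontal axis). Points are libraries, short lines are group means and bars are the SD of 3 libraries, with EV of the Ezh2 series at 1.11, 0.778 and 0.305 on days 0, 1 and 4 and EV of the Suz12 series at -0.051, -0.012 and 0.06.

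The deposited gene lists were compared with the calls from the same libraries, so they are not independent of them. Of the tested genes listed as up in WTvsKO on days 0, 1 and 4, 94.9%, 97.3% and 99.4% of 919, 813 and 518 were called higher in EV. Of those listed as down, 373 of 373, 272 of 273 and 237 of 238 were called lower. "Up" in these lists therefore stands for higher in EV than in WT. For WTvsamKR, 89 of 236, 43 of 158 and 55 of 59 tested gene IDs listed as up were called higher in amKR. All of them had a log2 change above 0, with medians of 1.33, 1.43 and 1.39, so those not called missed the threshold and did not go the other way. Of those listed as down, 33 of 33, 3 of 6 and 10 of 14 were called lower.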

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

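The tests of the retinoic acid pattern and the joint fit of both series were chosen after the values were seen, as were the splits with the line effect removed, while the plain splits of the libraries were planned.

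The effect of a line differed between days in 3 comparisons, each tested as a difference between the day 4 and day 0 effects. EV of the Ezh2 series differed in 1751 genes. The growth factor gene Hbegf (2.25), the adhesion receptor gene Adgrd1 (6.71), the cell junction genes Cdh1 (1.59) and Dsg2 (1.60), and Myof (1.36), which repairs membranes, moved upward on the log2 scale. Ddr2 (-5.36), Pck2 (-3.02), Bcat1 (-2.81), the scaffold gene Iqgap2 (-3.29) and Sox11 (-4.90) moved downward, and Ezh2 moved by 0.89. Of 100 splits of the 12 libraries, 1 gave as many genes, the real one, at 1209 in a fit of these libraries alone against 1144 in the next. That next split swaps all 6 day 0 libraries between the lines and changes 2 labels of day 4, so it adds the day 0 line effect to part of that of day 4 where the real split subtracts it. Plain splits therefore do not measure the difference between days. With the line effect of both days removed through an offset, the real split gave 1209 and the next 864, with 1 of 100 as large. The offset was fitted with the real labels, and the libraries of a group may share a culture. The test therefore speaks only for a random grouping of these libraries and not for chance between cultures or lines. EV of the Suz12 series gave 1282 genes against 370 in the next of 100 plain splits, with 1 as large. With the line effect removed the next gave 166, again with 1 as large, and the same limits hold.

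EV of the Suz12 series differed between days in 998 genes. Suz12 moved by 1.84, Apoe by 1.09, Dlk1 by 3.76, Fzd2 by 2.06 and Sox2 by 1.67. The thrombin receptor gene F2r moved by -1.20, Rhox5 by -1.81, Vim by -0.90 and Tfpi, which inhibits coagulation, by -1.14. The amKR effect differed between days in 22 genes. The metallothionein gene Mt2 (1.25), Clcn5 (1.13), the G protein gene Gng12 (1.15), Tdh (0.98) and the mesendoderm factor gene Eomes (1.30) moved upward, and Ebf1 (-2.41), Hsf2bp (-1.19), the lipase gene Lpl (-1.29), Zfhx2 (-0.81) and the actin regulator gene Lima1 (-0.69) downward. Tdh, Lpl, Zfhx2 and Lima1 lost their call when some single libraries were left out, and Eomes lost it without WT day 4 replicate 1. In the amKR test 4 of 100 plain splits gave as many genes as the real one, which gave 47 in that fit. The highest other split gave 2336. It keeps every day 0 label and changes 4 day 4 labels, which moves most day 4 libraries to the other line, so it adds part of the day 4 line effect to that of day 0 where the real split subtracts it. The structure it points to may thus be the lines themselves. With the line effect removed 1 of 100 splits, the real one, gave 47 or more, and the highest other gave 14. The limits given for EV hold here too. The 22 calls of the fit over all libraries went down to 8 without WT day 4 replicate 1. For ddim 19 of 100 plain splits gave at least the 1 gene of the real one, the highest 56, and 12 of 100 did with the line effect removed, the highest 2, so chance is not excluded.

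WT cells of the 2 series changed differently after the switch to medium with retinoic acid. No group was kept without retinoic acid after day 0, so its effect is not separated from that of the change of medium. In a joint fit of their WT libraries the change from day 0 to day 1 differed in 7639 of 14154 genes and that to day 4 in 5757. Hoxb1 and Cyp26a1, direct targets of retinoic acid, stood at 0.0749 and 2.06 CPM in WT of the Ezh2 series on day 1 and at 339 and 378 CPM in the Suz12 series. Day 0 cells labelled day 1 are argued against by the 46.5% of tested genes called between the days. Other wrong labels were not tested. A lack of PRC2 activity in that WT line would slow the response wherever the complex is lost, but EV of the Suz12 series gave a list median of 4.2 (95% interval 2.08 to 5.46) on day 1, which argues against it. EV and amKR of the Ezh2 series also showed no clear day 1 rise, at 0.1 (95% interval -0.55 to 2.31) and -0.14. The pattern is thus not one of WT alone. The list was higher in EV than in WT (adjusted p 0.0168). A difference between the series in handling or starting state stays open. The list's day 1 median was 3.56 higher in WT of the Suz12 series. No test here separates a series from its handling, since each is a single set of lines. Depth was planned as a further test for this pattern and was not run.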

How the results depend on the processing

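The removal of 3 EV libraries, the offset by chromosome median, the overlaps off chromosomes 6 and 8 and leaving out libraries for the gene lists were chosen after seeing the data, and the other alternatives were planned. No named gene or gene list changed direction past the threshold under any of them. Of 876 named results, DESeq2 and no filter ended 10 calls each, only the libraries compared 33, the replicate block 4 and RLE size factors 3. Leaving out one library ended 434 of 5526, without the 3 EV libraries 2 of 233 ended, and the chromosome offset ended 19 of 578. The replicate block within line ended none of 298. Among 442 list results, the replicate block ended 3, an estimated correlation ended 47 and added 1, fry, which tests a list against no change and so asks another question, did not pass 9 and passed 97 more, and leaving out one library ended 85 and added 54 of 3060.

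Counts of genes that moved by over 1.5 times follow, and the cause was not tested. DESeq2 called 389 genes for amKR against WT on day 1 (230) and 51 for the amKR effect between days (22). No filter, which tests more genes, gave 501 and 83 for these, and 61 (9) and 48 (22) for ddim on days 1 and 4. With only the libraries compared in the fit, EV on day 4 of the Ezh2 series gave 1515 (2510), amKR on days 0 and 1 1807 (631) and 671 (230), and the amKR effect between days 47. In the Suz12 series that fit gave 625 (1143) and 1857 (1104) for EV on days 1 and 4, 0 (9) and 187 (22) for ddim on days 1 and 4, 1362 (907) for ddim against EV on day 1 and 1 (0) for the ddim effect between days. The share called higher moved by over 10 points in a few cases: amKR on day 0 to 65.4% from 54.5% and the amKR effect to 62.7% from 77.3% with no filter, amKR on day 1 to 77.9% from 64.3% with only the libraries compared, and ddim on day 1 from 44.4% to 55.7% with no filter and to 54.5% with the replicate block or the chromosome offset.

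Leaving out one library gave 151 to 426 genes for amKR on day 0, 55 to 194 on day 1 and 84 to 239 on day 4, and 8 to 18 for the amKR effect between days. In the Suz12 series it gave 687 to 1260 for EV on day 1 and 656 to 844 on day 4, 0 to 1, 0 to 90 and 9 to 12 for ddim on days 0, 1 and 4, and 576 to 618 and 1041 to 1406 for ddim against EV on days 1 and 4. Lists past the threshold then numbered 1 to 3 for amKR on day 0, 5 to 11 on day 4, 4 to 9 for the EV effect between days of the Ezh2 series, 0 to 1, 0 to 1 and 1 to 7 for ddim on days 0, 1 and 4, 5 to 8 for ddim against EV on day 0 and 1 to 5 for the ddim effect between days.

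With fry, lists past the threshold in the Ezh2 series were 17 (7) for EV on day 0, 10 (4) on day 4, 3 (1) for amKR on day 0, 6 (3) on day 1, 12 (6) for amKR against EV on day 4, 13 (7) for WT on day 1 and 14 (8) for the EV effect between days. In the Suz12 series they were 9 (5), 13 (5) and 8 (3) for EV on days 0, 1 and 4, 2 (6) for ddim on day 4, 8 (5) and 11 (7) for ddim against EV on days 0 and 4, 17 (11) for WT on day 1, 7 (3) for the EV effect and 1 (4) for the ddim effect between days. With an estimated correlation they were 0 (1), 1 (3) and 4 (9) for amKR on days 0, 1 and 4, 3 (7) for WT on day 1, 3 (8) for the EV effect in the Ezh2 series, 2 (6) for ddim and 3 (7) for ddim against EV on day 4, and 1 (4) for the ddim effect.

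The signature without a fold minimum gave 0.406, 0.381 and 0.164 for EV of the Ezh2 series on days 0, 1 and 4, 0.042 and 0.098 for amKR on days 0 and 1, -0.001, 0.021 and 0.004 for EV of the Suz12 series and 0.005 for ddim on day 1. A prior count of 0.5 gave 1.374, 0.976 and 0.404 for EV of the Ezh2 series, 0.224 and 0.21 for amKR on days 0 and 1, and -0.104 and 0.08 for EV of the Suz12 series on days 0 and 4. The day 0 signature gave 0.995 and 0.428 for EV of the Ezh2 series on days 1 and 4, 0.218 and 0.126 for amKR, 0.023 and 0.141 for EV of the Suz12 series, and 0.003 for ddim on day 1. The cause of these shifts is the choice of genes or of prior count. At an adjusted p of 0.01, which calls fewer genes, EV and amKR shared 63 higher and 45 lower genes on day 0, 26 and 15 on day 1 and 29 and 22 on day 4, and EV and ddim shared 1 lower gene on days 1 and 4. Off chromosomes 6 and 8, which leaves fewer genes, EV and amKR shared 112, 21 and 36 lower genes on days 0, 1 and 4, against 186, 47 and 64. At an adjusted p of 0.01 EV of both series shared 144 and 57, 64 and 12, and 52 and 24 genes. Depth limits the weak genes, since 0 counts in a group allow up to 0.198 to 0.259 CPM.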

Other observations

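The tests of the loss of PRC2 function on chromosome 6 and of the Ezh1 and Hprt counts, except the deletion past Ezh1, were chosen after the values were seen, as was the set of explanations weighed.

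Chromosomes 6, which holds Ezh2, and 8 were lower in Ezh2 series EV and amKR than in WT on each day, with 95% intervals below 0 (here over genes, not libraries). On chromosome 8 the median log2 change was -0.064, -0.108 and -0.109 in EV and -0.123, -0.114 and -0.102 in amKR on days 0, 1 and 4, and no explanation was tested for it. Chromosome X was higher in EV of the Ezh2 series, at 0.139, 0.253 (95% interval 0.206 to 0.316) and 0.068, and lower in EV of the Suz12 series on day 0, at -0.149 (95% interval -0.199 to -0.096). Chromosomes 1, 3, 12, 13, 14 and 19 were above 0.1 in EV of the Ezh2 series on days 0 and 1, chromosomes 2 and 16 on day 1 and chromosome 19 on day 4, also untested. On chromosome 6 it was -0.273 in EV and -0.18 in amKR on day 0, -0.253 and -0.087 on day 1, and -0.334 and -0.154 on day 4. A loss of PRC2 function would lower chromosome 6 in the Suz12 series too, but its EV gave 0, -0.015 and -0.019, which argues against it. A bias by gene length or expression is argued against by the median of -0.371 (95% interval -0.417 to -0.296) left after that trend was removed, in a test whose centring was changed after a first look. A difference in copy number between the lines is consistent with the genes not called in amKR on day 0, whose medians were -0.156 on the proximal part of the chromosome and -0.133 on the distal part. In EV the distal part gave -0.144 and the proximal part -0.082, with an interval that reaches 0.034. The calls against WT in the Ezh2 series may therefore hold some chromosome 6 genes that follow copy number.

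Ezh1 and Hprt were counted in EV of the Ezh2 series on every day and hardly at all in WT or amKR. WT held 3.36% of the Ezh1 counts that reads shared with Ezh2 would give by the EV ratio, and loss of PRC2 function left Ezh1 with an upper bound of 0.43 on its log2 change in EV of the Suz12 series, so both are argued against. A deletion that reaches past Ezh1 is argued against by the median of 0.07 (95% interval -0.53 to 0.28) of the 12 tested genes within 100 kb. Ramp2 is the only one of these called (log2 change 3.11 ± 0.94, adjusted p 0.0118) and moved as such a deletion would have it, but it was counted in WT on day 4, at 5.3 CPM, and was chosen after its values were seen. It stays open that the EV libraries hold cells of another origin than the WT and amKR libraries, which 7 genes might show: Ezh1, Hprt, Rpl29, Acp1, 5730507C01Rik, Gm10073 and Gm42047, on 5 chromosomes, were counted in EV and in every group of the Suz12 series at 5 CPM or more and were at least 4 times lower in WT and amKR. They were not absent there, since means in WT and amKR reached 4.5 CPM for Acp1, 3.84 for Rpl29 and 2.14 for Gm10073. No gene met the reverse rule, and Rpl29, Gm10073 and Gm42047 have copies elsewhere or are predicted genes, so their reads are uncertain. The rule behind these 7 genes is one of 12 settings tried, which gave from 1 to 9 genes, and the genes were chosen after their values were seen. If the origin differs, every comparison with EV of the Ezh2 series holds that difference too.

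Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In fits of only the libraries compared, the real split and the highest other gave the following numbers of genes. For EV against WT in the Ezh2 series these were 3733 and 0 on day 0, 3330 and 0 on day 1, and 1515 and 59 on day 4. For amKR against WT they were 1807 and 0, 671 and 3, and 233 and 425, where 2 splits were as large as the real one. For amKR against EV they were 2432, 1613 and 1079, each with 0 in the highest other split, and the WT time course gave 7032 on day 1 and 7763 on day 4 with 0 in the others. In the Suz12 series EV against WT gave 1657, 625 and 1857, ddim against EV gave 1313, 1362 and 2298, and the WT time course gave 8377 and 10881, again with 0 in the highest other. For ddim against WT the real split gave 0 on day 0 with 7 in the highest other, 0 on day 1 with 0, and 187 on day 4 with 3. All 10 splits were as large as the real one for ddim on days 0 and 1, and 1 of 10, the real one, was in each other comparison but amKR against WT on day 4.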
